A study of Homo sapiens with 6 samples.

How the data were processed

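Small RNA was sequenced from human dermal fibroblasts (HDF), primary connective tissue cells of the skin, after 48 h on polydimethylsiloxane (PDMS) of 3 kPa or 30 kPa. PDMS is a silicone elastomer whose stiffness can be set, and both substrates were coated with 1% fibronectin, an extracellular matrix protein that cells attach to. Per the labels, 4 dishes were made for each stiffness, RNA of 15 to 31 nt was cut from a denaturing gel, and libraries followed Illumina protocols. There were 3 libraries per stiffness. The labels give replicate numbers without saying whether these are separate cultures, dishes or preparations, so p-values measure only the spread between these libraries, which may be technical. The series title names endothelial cells and the growth medium is an endothelial one, whereas each sample is labelled as dermal fibroblasts. The sample labels were followed, and markers of both cell types are reported.

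The submitters' processing notes name Salmon, STAR and the genome build GRCh38, with no versions, and trimming, alignment settings and strand settings are not given in the sources used here. Each deposited table holds 2813 rows, 1 per mature microRNA locus, with 2588 distinct mature microRNA names. The deposited values are estimated counts, which need not be whole, and TPM. The estimated counts were used and the deposited TPM was not tested. Rows carry GRCh38 coordinates, and the length given in the table is 1 nt shorter than the span from start to end in each of the 2813 rows. All 2813 rows lie inside a microRNA hairpin on the same strand in GENCODE release 29, which uses GRCh38, and mature sequences and overlapping genes were taken from it. A mature microRNA encoded at several loci has several rows among which the estimated counts could be divided, so the value of any single copy is uncertain. Rows on opposite strands of 1 locus are uncertain for the same reason, because the strand setting is not given. Rows of the Y chromosome stayed in library totals and tests and are not reported one by one.

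Estimated counts were rounded to whole numbers. The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM scaling, the default low-count filter, a model of stiffness only and no robust option. Benjamini-Hochberg adjustment was applied over the 2613 rows tested, with a threshold of 0.05. Log2 fold changes are coded as 30 kPa minus 3 kPa, and their standard errors (SE) come from the coefficient and its test statistic. CPM values are counts scaled to the library total after TMM. A TMM factor below 1 raises the CPM values of a library, and the factors ranged from 0.325 to 2.09.

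Before the data were examined, 30 microRNA lists (families, genomic clusters, functional groups and cell type markers), the tests and most alternatives were fixed. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log CPM with a preset correlation of 0.01, and again with an estimated correlation and with fry. Summed CPM per list and the share of counts taken by the 10 most counted rows were compared by two-sided exact permutation tests, for which 3 against 3 libraries cannot give a p below 0.1. Arm usage was log2 of the 5p over the 3p count with a pseudocount of 0.5, in hairpins with a mean of at least 10 counts on each arm, tested with limma. The rule for named microRNAs allowed up to 12 higher and 12 lower with the largest fold change among those past the threshold with a mean of at least 10 CPM and no overlap between groups. With fewer than 10 of these it added the smallest unadjusted p until 10 were named. It also allowed the 5 highest mean CPM, up to 4 abundant members per list, and miR-21, miR-126, miR-143, miR-145 and the miR-29 family.

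Alternatives were other scalings (DESeq2 size factors, total count, upper quartile), DESeq2 1.42.0 and limma-voom as tests, other low-count filters, identical mature microRNAs collapsed, the replicate number as a block, and each library left out in turn. The files hold only microRNA rows, so the planned test on all rows is identical and was not run, and the alternatives planned for normalized values did not apply. Fits without the rows or libraries dominated by 1 row, and without rows that match the reverse complement of another row over 11 bases, and the other set tests within alternative fits, were chosen after seeing the data.

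The edgeR step was tested on simulated counts for the comparison of 30 kPa with 3 kPa over 2613 rows, 200 of them changed. Each simulation used a single dispersion for all rows and libraries. At the common dispersion seen in the data (0.476), 0 of 65 rows changed by 1 (log2), 2 of 65 changed by 2 and 22 of 66 changed by 3 were recovered, with 0 false calls. Rows with a mean of at least 10 CPM, fitted alone, had a common dispersion of 0.792, so this recovery need not hold for abundant microRNAs. At a dispersion of 0.05, 41 of 67, 65 of 67 and 66 of 66 were recovered, with 13 false calls among 185. Exact binomial intervals (95%) on shares cover counting error only, since reads are not independent molecules.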

Results

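MicroRNA abundance was compared between dermal fibroblasts kept for 48 h on a soft (3 kPa) and a rigid (30 kPa) substrate, to describe the microRNA profile at each stiffness. There were 3 libraries at each stiffness. Total estimated counts were 14518517, 11581386 and 15989119 in 3 kPa replicates 1, 2 and 3, and 7806565, 13288416 and 18855585 in 30 kPa replicates 1, 2 and 3. Between 2686 and 2756 of the 2813 mature microRNA loci had a count in each library.

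Abundant microRNAs included miR-21-5p, which is raised in fibrotic tissue, miR-100-5p and miR-222-3p. miR-21-5p (chromosome 17, 59841273 to 59841294, in an exon of VMP1) had 37446 ± 23568 CPM at 3 kPa and 70276 ± 71082 CPM at 30 kPa (mean ± SD, n = 3 each), a log2 fold change of 0.91 (SE 1.51). miR-100-5p (intron of MIR100HG) had 30279 ± 20070 and 63236 ± 70821 CPM (1.06, SE 1.52), and miR-222-3p (intron of MIR222HG) had 18324 ± 12402 and 30768 ± 31574 CPM (0.75, SE 1.51). These log2 fold changes were smaller than their SE, with an adjusted p of 0.995 in edgeR for each. Without 30 kPa replicate 3 the log2 fold changes were -0.16, -0.31 and -0.37, and with scaling by total count alone they were -0.36, -0.41 and -0.58. The level of miR-21-5p was 10298 CPM in 3 kPa replicate 2 and 3652 CPM in 30 kPa replicate 1, and between 49368 and 145105 CPM in the other 4 libraries.

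**Figure D1:**
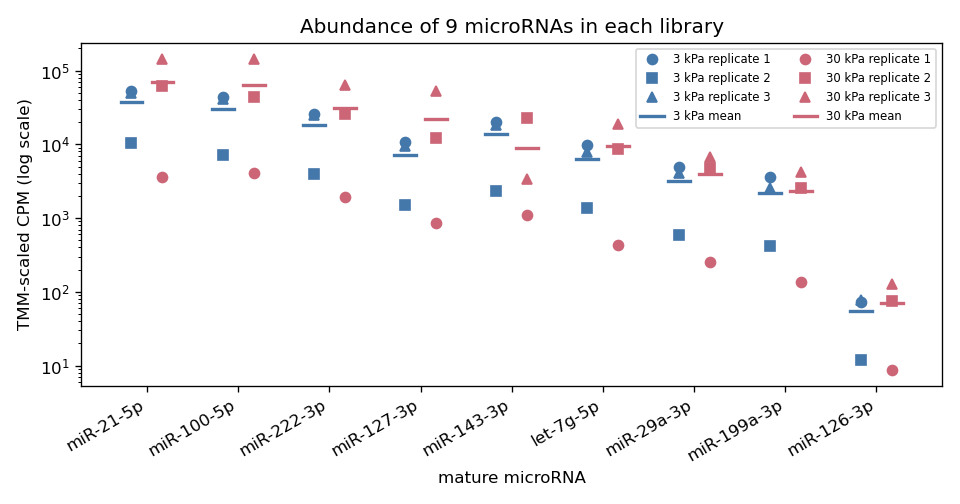
CPM after TMM scaling (log axis) of 9 microRNAs, with 1 point per library, 3 kPa in blue, 30 kPa in red, marker shape for the replicate number and a bar for the mean of 3 libraries. For miR-21-5p, 3 kPa replicate 2 (10298 CPM) and 30 kPa replicate 1 (3652 CPM) lie below the other 4 libraries.

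A single locus held most of the counts in 3 of the 6 libraries. In 3 kPa replicate 2, miR-4697-5p (chromosome 11, 133898551 to 133898572, in an exon of MIR4697HG) took 92.8% of the counts (95% exact interval 92.8 to 92.8). In 30 kPa replicate 1, miR-212-3p (chromosome 17, 2050290 to 2050310, in no host gene) took 78.8% (interval 78.7 to 78.8). In 30 kPa replicate 3, miR-4637 (chromosome 5, 14825932 to 14825953, in an intron of ANKH) took 70.0% (interval 69.9 to 70.0). None of these 3 exceeded 0.122% of any other library. The counts left for all other loci were 833586, 1657435 and 5663385 in these libraries. The most counted locus elsewhere was miR-21-5p at 10.6% (3 kPa replicate 1) or miR-4668-5p at 11.7% (3 kPa replicate 3) and 16.3% (30 kPa replicate 2). The 10 most counted loci held 68.3% ± 23.9 (SD, n = 3) of the counts at 3 kPa and 79.5% ± 16.2 (SD, n = 3) at 30 kPa, a difference smaller than the spread between replicates (two-sided exact permutation p = 0.6).

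**Figure D2:**
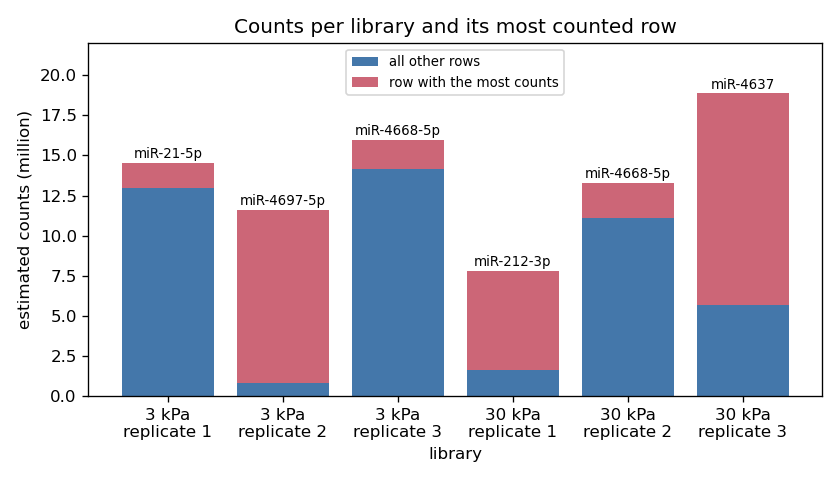
Estimated counts per library, with the most counted locus in red and all other loci in blue. The red part is 92.8%, 78.8% and 70.0% of the bar in 3 kPa replicate 2, 30 kPa replicate 1 and 30 kPa replicate 3, and at most 16.3% in the other libraries.

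Libraries did not group by stiffness. For this comparison the 3 loci that held most of the counts of a library were left out. Counts were scaled to the remaining totals without TMM, and 506 loci with a mean log2 abundance above that of 50 CPM were used. Across them, 3 kPa replicate 3 correlated at r = 0.980 with 30 kPa replicate 2 and at r = 0.973 with 3 kPa replicate 1. The correlations of 30 kPa replicate 1 with 30 kPa replicates 2 and 3 were 0.393 and 0.341. Loci are not independent replicates, and these values describe the libraries only. All 6 were kept as separate libraries, as the chi-square per degree of freedom, which covers counting error only, was at least 146 in each pair. Unlike the correlations, it was computed on unscaled counts of all but the least counted loci, with the 3 loci left out above included.

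The comparison of 30 kPa with 3 kPa gave 0 microRNAs higher and 0 lower past the threshold among 2613 tested with edgeR. At an unadjusted p under 0.05, 39 were higher and 26 lower. limma-voom also gave 0, and DESeq2 gave 1 lower, a copy of miR-3913-5p. The groups did not overlap for 130 loci (4.98%), where chance gives 10%. With the common dispersion of these libraries (0.476) given to all loci, 0 of 65 simulated changes of 1 (log2) and 2 of 65 of 2 were recovered. Changes of these sizes would rarely or never have been detected at that dispersion, from which single loci differ. Without the 3 libraries with a dominant locus, a comparison of 2 libraries with 1 chosen after seeing the data, edgeR gave 5 higher and 0 lower, with the lone 30 kPa library assumed to vary like the pair at 3 kPa. These 5, named after their values were seen, were miR-552-3p (log2 fold change 5.86), miR-3194-5p (4.13), miR-1288-3p (4.11), miR-4528 (3.47) and miR-6879-3p (3.12). Each was highest in 30 kPa replicate 2, where miR-552-3p had 322 CPM against at most 7.50 in the other 5 libraries. Without 30 kPa replicate 2, edgeR gave 1 higher, miR-338-3p (adjusted p 0.0474). Both libraries then left at 30 kPa have a dominant locus, so stiffness cannot be told apart from it in that fit.

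The 10 microRNAs with the smallest unadjusted p had an adjusted p in edgeR of 0.496 (miR-3913-5p) or 0.995 (the other 9). The copy of miR-3913-5p at chromosome 12, 69584744 to 69584765, had 90.1, 9.23 and 102 counts at 3 kPa and 0, 6.08 and 0 at 30 kPa, a log2 fold change of -4.22 (SE 0.76). The other copy, at 69584780 to 69584801, had a log2 fold change of 0.35 (SE 0.65), and with both copies collapsed the value was -0.045. miR-4528 (intron of DCC) had 1.45 ± 1.07 CPM at 3 kPa and 5.54 ± 3.20 CPM at 30 kPa (2.13, SE 0.61). miR-6819-3p (intron of MYH9) had 17.8 ± 6.21 and 4.76 ± 1.35 CPM (-1.89, SE 0.62). A copy of miR-3202 had 2.93 ± 0.258 and 0.571 ± 0.789 CPM (-2.57, SE 0.82), and 0.59 with its copies collapsed. The other 6 were high in 1 library each. miR-520f-5p (9.04, SE 2.82), miR-499a-3p (4.35, SE 1.496) and miR-4637 (12.71, SE 4.01) were high in 30 kPa replicate 3, and without it their log2 fold changes were -0.065, -0.17 and -0.25. miR-4697-5p (-11.66, SE 3.87), miR-496 (-7.40, SE 2.51) and miR-6733-3p (-6.49, SE 2.26) were high in 3 kPa replicate 2, where miR-496 had 1845 CPM against at most 6.21 CPM elsewhere.

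Among microRNAs tied to matrix and contractile genes, 0 rose and 0 fell. The miR-29 family, which represses collagen genes, had 4 tested loci, all 4 not past the threshold. miR-29a-3p had 3208 ± 2314 CPM at 3 kPa and 3907 ± 3303 CPM at 30 kPa (log2 fold change 0.28, SE 1.48). The most abundant copy of miR-29b-3p had 8.83 ± 5.03 and 15.1 ± 14.2 CPM (0.76, SE 0.92), and miR-29c-3p 5.59 ± 1.48 and 6.43 ± 1.51 CPM (0.19, SE 0.46). Of the cluster of miR-143 and miR-145, abundant in smooth muscle, 4 of 4 loci were not past the threshold. miR-143-3p had 13660.5 ± 9852 and 9041 ± 11848 CPM (-0.60, SE 1.52), and miR-145-5p 498 ± 441 and 685 ± 747 CPM (0.46, SE 1.47). With scaling by total count alone the median over all loci moved from 0.12 to -0.52, and the values of miR-29a-3p, miR-29b-3p, miR-29c-3p and miR-145-5p turned negative. Of 14 loci of fibrosis-associated microRNAs, 14 were not past the threshold. Of 18 loci of microRNAs reported to target CCN2, a matricellular protein gene, 18 were not past it, with 5 values above 0, 13 below and a median of -0.23. The CCN2 list had the smallest camera p of all lists (adjusted p = 0.0848 in limma, and adjusted p = 0.987 with an estimated correlation). Of its loci, the 10 that match the reverse complement of another locus over 11 bases were all below 0, and of the 8 others 5 were above 0 and 3 below. Over all 2813 loci, 926 have such a match. In the fit on loci without such a match, the direction of camera for these 8 was still downward (camera p 0.0461, adjusted p 0.384 in limma). With camera the CCN2 list passed downward with total count scaling (adjusted p 0.0036 in limma). It also did so without 3 kPa replicate 2 (0.0049), 30 kPa replicate 2 (0.0127) or 30 kPa replicate 3 (0.0013), and its direction turned upward without 30 kPa replicate 1 (0.532). In each fit where it passed, it did not with an estimated correlation (lowest adjusted p = 0.723) or with fry (lowest 0.829).

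In the let-7 family, 12 of 12 loci were not past the threshold, with 4 values above 0 and 8 below. let-7g-5p had 6302 ± 4385 CPM at 3 kPa and 9342 ± 9215 CPM at 30 kPa (log2 fold change 0.57, SE 1.52), and the most abundant copy of let-7a-5p 4641 ± 3175 and 2576 ± 2790 CPM (-0.85, SE 1.44). In the miR-30 family, 6 of 6 loci were not past the threshold and had values below 0, among them miR-30d-5p (-0.57, SE 1.46) and miR-30a-5p (-0.55, SE 1.40). All 6 miR-30 loci and the 8 let-7 loci below 0 match the reverse complement of another locus over 11 bases. The 3 let-7 loci without a match were above 0. With camera both families passed downward with total count scaling (adjusted p 0.0036 in limma for each), with a mean of at least 10 CPM (0.0485 for each) and without 30 kPa replicate 3 (0.0211 for each). They also did so without 3 kPa replicate 2 (let-7 0.00086, miR-30 0.0104) or 30 kPa replicate 2 (let-7 0.0062, miR-30 0.0218). Neither passed in any of these fits with an estimated correlation (lowest adjusted p = 0.723) or with fry (lowest 0.829), and the direction turned upward without 30 kPa replicate 1 (let-7 0.367, miR-30 0.769). The imprinted 14q32 cluster had 93 tested loci, all 93 not past the threshold, with 73 values above 0 and a median of 0.48. With camera it passed upward without 30 kPa replicate 1 (adjusted p 1.4e-10 in limma), but not with an estimated correlation (0.671) or with fry (0.903). The direction of camera turned downward without 30 kPa replicate 3 (0.0624) and without 3 kPa replicate 2 (0.580). Its summed level was 32899 ± 13663 CPM at 3 kPa and 76260 ± 48807 CPM at 30 kPa (n = 3 each, two-sided exact permutation p = 0.2). The log2 ratio of these sums was 1.21, but -0.045 with total count scaling and 0.57 without 30 kPa replicate 3. Its member miR-127-3p had a log2 fold change of 1.61 (SE 1.61), which was -0.13 without 30 kPa replicate 3 and -0.047 with total count scaling. In the families of miR-100, miR-125 and miR-199, with 5, 3 and 8 tested loci, 0 passed. miR-99b-5p had a value of 1.36 (SE 1.57), and the most abundant copies of miR-125b-5p and miR-199a-3p had -0.89 (SE 1.41) and 0.08 (SE 1.47).

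The remaining families and clusters also had 0 members that rose and 0 that fell. Tested loci numbered 29 for the miR-17/92 cluster and its paralogs, 5 for the miR-17 seed family, 3 for the miR-19 seed family and 8 for the family of miR-15 and miR-16. They numbered 5 for miR-130 and miR-301, 12 for the clusters of miR-23, miR-27 and miR-24, 6 for miR-181, 4 for miR-34 and miR-449, and 4 for miR-221 and miR-222. The Xq26 cluster of miR-424 and miR-503 had 12, the C19MC and miR-371 clusters 62, and the inflammation and hypoxia list 8. The inflammation and hypoxia list summed to 41123 ± 24311 CPM at 3 kPa and 375270 ± 462290 CPM at 30 kPa (two-sided exact permutation p = 0.1, the smallest possible), and it holds miR-212-3p. Without 30 kPa replicate 1 these sums were 43232 and 102310 CPM, and the log2 ratio moved from 3.19 to 1.24. The exact permutation p of this list was 0.4 with total count scaling and 0.5 without 3 kPa replicate 1, 2 or 3.

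With camera, 0 of the 29 lists tested passed, and 0 passed with an estimated correlation or with fry. Adjusted over the list alone, 0 loci passed in 29 lists and 1 in the hepatocyte markers, where 2 loci were tested. That locus, miR-122-3p (smallest adjusted p 0.0478 in edgeR), had 30.7 CPM in 30 kPa replicate 1 and at most 0.821 CPM elsewhere. The direction of camera was opposite to the sign of the median for the miR-17/92, miR-17, miR-19, miR-15, miR-23, miR-181, miR-143, miR-199, fibrosis, inflammation, fibroblast, striated muscle and neural lists. The camera counts, which set a list against the other loci, changed when 1 library was left out. Without 3 kPa replicate 2, 7 lists passed downward, and without 30 kPa replicate 1, 6 passed upward. Without 30 kPa replicate 2, 3 passed downward and 1 upward, and without 30 kPa replicate 3, 5 passed downward. The fibroblast list passed downward without 3 kPa replicate 2 (adjusted p 0.0165 in limma) and without 30 kPa replicate 3 (0.0023), and upward without 30 kPa replicate 1 (4.9e-05). In each of these 4 fits 0 lists passed with an estimated correlation (lowest adjusted p = 0.671 among the lists named by camera) and 0 with fry (lowest 0.0837, for the pluripotent list without 30 kPa replicate 2). An upward camera call was not always a higher sum, as the Xq26 list without 30 kPa replicate 1 had 1757 CPM at 3 kPa and 1541 CPM at 30 kPa.

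Markers of fibroblasts and mesenchymal cells, with 20 tested loci not past the threshold, summed to 33368 ± 23773 CPM at 3 kPa and 48540 ± 44497 CPM at 30 kPa (n = 3 each, two-sided exact permutation p = 0.7). By library the sum was 51109, 6356 and 42639 CPM at 3 kPa and 2902, 50916 and 91801 CPM at 30 kPa. The endothelial list, with 4 tested loci, summed to 66.2 ± 41.0 and 83.3 ± 63.4 CPM (exact permutation p = 0.8). Its member miR-126-3p, encoded in an intron of EGFL7, had 54.4 ± 36.9 and 71.3 ± 60.6 CPM (log2 fold change 0.39, SE 1.19). Of 13 epithelial and keratinocyte, 11 haematopoietic, 8 striated muscle, 11 neural and 14 pluripotent loci, 0 rose and 0 fell. Epithelial and keratinocyte markers summed to 69.9 ± 3.22 CPM at 3 kPa and 86.1 ± 22.4 CPM at 30 kPa (exact permutation p = 0.4), and haematopoietic markers to 355 ± 289 and 227 ± 194 CPM (exact permutation p = 0.5). Sums for striated muscle markers were 17.9 ± 3.04 and 21.1 ± 3.53 CPM (exact permutation p = 0.3), and for neural markers 44.0 ± 8.67 and 45.0 ± 22.2 CPM (exact permutation p = 1). Pluripotent markers summed to 22.3 ± 1.65 and 36.2 ± 11.05 CPM (exact permutation p = 0.1, the smallest possible), and with total count scaling the direction turned, to 34.7 and 31.2 CPM (exact permutation p = 0.8).

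Arm usage, the balance of the 5p and 3p products of a hairpin, was tested in 827 hairpins. With limma, 0 hairpins shifted toward the 5p arm and 0 toward the 3p arm, and 6 had an unadjusted p under 0.05. Without 30 kPa replicate 2, the hairpin of miR-338 shifted toward the 3p arm (adjusted p 0.0157) and that of miR-3150b toward the 5p arm (adjusted p 0.0422). Both hairpins were named after their values were seen. The libraries left at 30 kPa in that fit, replicates 1 and 3, each have a locus that took most of the counts.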

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

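The fits without dominant loci, without the libraries that hold them and without antisense matches were chosen after seeing the data, as were the set tests within alternative fits. The count of 0 differing microRNAs held with DESeq2 size factors, total count, upper quartile, limma-voom, no low-count filter, collapsed copies, without the dominant loci and without antisense matches. It was 1 with DESeq2 (a copy of miR-3913-5p, adjusted p 0.00122 against 0.496 in edgeR), 2 with a mean of at least 10 CPM (miR-3184-3p and miR-520f-5p, both high in 30 kPa replicate 3 alone) and 5 without the 3 libraries with a dominant locus. Leaving out 1 library gave 0 to 1, the 1 (miR-338-3p) without 30 kPa replicate 2, where both 30 kPa libraries left have a dominant locus. Lists past the threshold numbered 0 in most settings, 3 with total count, 2 with at least 10 CPM and 0 to 7 when 1 library was left out. In each fit in which camera passed a list, 0 lists passed with an estimated correlation and 0 with fry. Lists at the smallest exact p numbered 2, 0 with total count and 0 to 6 with 1 library left out; hairpins with shifted arm usage 0 to 2. The cause was not tested. The difference in the share of the top 10 loci (11.1 points) was 3.56 without 3 kPa replicate 1 and 24.9 without 3 kPa replicate 2, moves smaller than the SD between replicates.

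With the replicate number as a block (replicate block), 0 microRNAs, 0 hairpins and 1 list (CCN2, camera adjusted p 0.0406) passed. In that fit the list had an adjusted p of 0.949 with an estimated correlation and 0.971 with fry. The log2 fold change of miR-4697-5p changed sign there, to 0.50. Deviations of same-numbered libraries correlated at -0.36, -0.49 and 0.22, within the range of differently numbered ones (-0.53 to 0.51). These few values cannot tell whether a number marks a shared culture or preparation.

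Of 28 named microRNAs, 6 kept their sign in each fit they entered. Filters left some out: 23 entered with a mean of at least 10 CPM and 18 without antisense matches. With total count the log2 fold change became -0.36 (miR-21-5p), -0.41 (miR-100-5p), -0.73 (miR-126-3p), -0.97 (miR-145-5p), -0.73 (miR-29a-3p), -0.44 (miR-29b-3p), -0.53 (miR-29c-3p), -0.68 (let-7g-5p), -0.58 (miR-222-3p), -0.27 (miR-99b-5p), -1.01 (miR-199a-3p) and -0.047 (miR-127-3p). With limma-voom it was -0.078 (miR-29a-3p), -0.075 (let-7g-5p) and -0.36 (miR-199a-3p), and with collapsed copies 0.59 (miR-3202). Without the 3 libraries with a dominant locus it was -0.094 (miR-4637), 0.055 (miR-4697-5p), 0.056 (miR-6733-3p), -0.18 (miR-212-3p), 0.26 (miR-143-3p), -0.40 (miR-145-5p), 0.053 (miR-30d-5p) and -0.21 (miR-199a-3p), and without the dominant loci -0.0074 (miR-199a-3p).

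Leaving out 1 library changed the sign of these values, whose ranges were -0.065 to 9.61 (miR-520f-5p), -0.25 to 13.72 (miR-4637), -12.56 to 1.61 (miR-4697-5p), -0.17 to 4.92 (miR-499a-3p), -0.23 to 9.45 (miR-212-3p), -0.16 to 1.30 (miR-21-5p), -0.31 to 1.43 (miR-100-5p), -0.34 to 0.76 (miR-126-3p), -0.81 to 1.38 (miR-145-5p), -0.33 to 0.74 (miR-29a-3p), -0.19 to 1.11 (miR-29b-3p), -0.43 to 1.01 (let-7g-5p), -1.56 to 0.0060 (miR-30a-5p), -0.37 to 1.13 (miR-222-3p), -0.31 to 1.75 (miR-99b-5p), -0.66 to 0.63 (miR-199a-3p) and -0.13 to 1.99 (miR-127-3p).

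The 3 counts that a count of 0 allows corresponded to between 0.159 and 0.384 CPM of the library totals (before TMM).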

Other observations

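The tests of explanations in this part were chosen after the results they concern had been seen, whereas the edgeR values come from the planned test. Among the most abundant loci outside the rule for named microRNAs, picked after their values were seen, miR-4668-5p had a mean of 45664 CPM, miR-4330 26875 CPM and miR-668-3p 16713.5 CPM. Their log2 fold changes were 0.83 (SE 1.36), -0.23 (SE 1.33) and 1.23 (SE 1.37), with an adjusted p of 0.995 in edgeR for each.

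In each of 3 libraries, 2 of them at 30 kPa, 1 locus took most of the counts. A response to stiffness is argued against, because the highest share of such a locus in another library of the same stiffness was 0.071%. A candidate explanation is reads of a sequencing adapter with its library index. miR-4697-5p, miR-212-3p and miR-4637 share 11, 13 and 11 bases with the Illumina small RNA adapter read across indexes 4, 11 and 8. For miR-4637 the match is to the reverse complement of the adapter. Of 2000 sets of 12 random index sequences, 0 gave as long a summed match (35 bases against at most 34). The p of this random-index test was 0.0005, the smallest it can give. The adapter, the indexes and both strands were picked with the loci in view, and an earlier Fisher exact test with a minimum of 11 bases set after seeing the matches (p = 2.7e-10) was dropped for that reason. Of 4 loci with a match of 10 bases, miR-4697-3p (4814 counts) and miR-5002-3p (6460) were highest in 3 kPa replicate 2. miR-552-3p (7982) was highest in 30 kPa replicate 2, while miR-590-3p was at most 267. Except for miR-5002-3p, these matches are to the reverse complement of the adapter. The match of miR-4697-3p mirrors that of miR-4697-5p, from the same hairpin, so it is not a separate match. Other loci were high in 1 of these libraries without a match of at least 10 bases across an index. They were miR-6733-3p (14892.5 counts) and miR-496 (9629) in 3 kPa replicate 2, and miR-520f-5p (3787) in 30 kPa replicate 3. Whether the adapter explanation extends to miR-552-3p was not tested.

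In 30 kPa replicate 3, loci with the same span on opposite strands had equal counts in 5 of 5 pairs with at least 10 counts (within 1%), for instance 438 for both miR-423-5p and miR-3184-3p, against 0 of 41 in the other 5 libraries (Fisher exact p = 7.3e-07). The 41 count the same loci again in several libraries, so they are not independent. The library was also picked after its values were seen, so the p-value does not support a cause. Counting that did not separate the strands in that library may account for the equal counts. Its estimated counts were whole numbers in 11.2% of loci, against 49.7% to 69.6% in the other 5 libraries. All opposite-strand pairs that overlap by at least 15 bases and hold at least 10 counts were also compared. Their median ratio of lower to higher count was 0.0125 to 0.0396 in the other libraries and 0.0192 in 30 kPa replicate 3. Loci matching the reverse complement of another over 11 bases were also low there, by -2.06 (log2; 95% bootstrap interval -2.36 to -1.55) as the mean over 5 classes of abundance, from 0.0063 in the lowest class to -3.66 in the highest. Equal sharing between 2 strands would cost no more than 1, so it is not the whole cause, and a response to stiffness is argued against by 30 kPa replicates 1 and 2 (the lower value was -0.0875). Match lengths of 9, 11, 13 and 15 bases were tried, with matching on abundance at 11 bases only, and without matching the difference at 11 bases or more was also below 0 in 30 kPa replicate 1 (-0.62 at 11 bases, -1.52 at 13 and -1.21 at 15) and in 3 kPa replicate 2 (-0.62 at 13 and -0.56 at 15).

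The absence of calls was set beside the 10 splits of the 6 libraries into 3 and 3. The real split gave 0 calls and the highest other 0, but with 0 calls in the real split all 10 of 10 give as many whatever the data, so this count decides nothing, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 65 loci and the split of the 3 libraries with a dominant locus from the other 3 gave 553. The remaining splits gave at most 268. The split by dominant locus was defined from these libraries, and 1 split in 10 is highest by chance, so the count decides no cause. The spread between libraries may come from the dominated ones: the only pair of one stiffness without a dominated library had a common dispersion of 0.0611, against 0.362 to 0.727 in the other 5 pairs, a rank that 1 pair in 6 has by chance. A first form of this test, over 9 fits of 2 libraries at 3 kPa against 1 at 30 kPa, was dropped because the pair at 3 kPa alone sets the spread there. Whether stiffness changes microRNAs by less than the spread seen here stays open.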
